A study of Homo sapiens with 12 samples.

How the data were processed

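Total RNA of 12 samples of H9 embryonic stem cells was compared on two-colour Agilent whole-genome arrays. Per the labels, Cy5 carried the sample and Cy3 a reference RNA pooled from embryonic stem cells in the undifferentiated and differentiated states and from fetal and newborn tissues. No dyes were swapped. Groups (control, 0.4, 2 and 4 Gy) and replicate numbers came from the sample titles. The series text describes 3 repeats of the experiment for each group. It does not say whether the repeats were separately kept cultures, so p-values measure the spread between these samples, which may be partly technical.

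Per the file headers and the submitters' processing notes, the scans were extracted with Agilent Feature Extraction 9.5.1. The deposited intensity values were the mean spot brightness and the median local background in each channel, as scanned. The deposited processed intensity values were background-subtracted, detrended and dye-normalized by lowess within each array, per the file headers. The deposited log10 ratio of each spot was that of processed Cy5 over Cy3, per the file headers. The deposited flags, 0 or 1 for each spot, marked spots well above background, saturated spots and outliers. The series matrix held log2 ratios of Cy5 over Cy3 by the authors, since its columns matched the log10 ratio converted to log2 with a slope of 1.00 and r of at least 0.9999. It was matched by probe for 29197 of its 29222 entries, its column medians ran from 0.0275 to 0.119, and nothing of its scale, centring or direction stayed unknown. The headers give hg18 as the build, and coordinates are those of the probes. Which exon a probe lies in was not analysed here.

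Each file had 45015 features, of which 43376 were not controls, for 41000 distinct probes. Background was corrected with normexp (offset 50) on the mean signals and the local background, and ratios were normalized by loess within each array, with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Outlier spots were left out and saturated spots kept. Spots of a probe were averaged. Probes well above background in Cy5 on fewer than 3 of the 12 arrays were left out, leaving 34113. Of several probes of a gene, the one with the highest mean signal over all arrays was kept, giving 25302 tested genes. Of the 41000 probes, 23680 were named through a RefSeq accession, 2802 by a current symbol and 1128 through an older symbol, while 13390 kept the name in the file. Of the tested genes, 9071 kept such a name.

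Group means were fitted by lmFit over all 12 arrays, so that the groups shared an estimate of the spread with 8 residual degrees of freedom, and contrasts were tested with eBayes and Benjamini-Hochberg adjustment at 0.05. Adjusted p values below are limma's. The comparisons were each dose against control, 2 against 0.4 Gy and 4 against 2 Gy. In all, 24 gene lists with 693 members, 669 of them tested, were fixed before the data were examined. They were tested with camera (preset correlation 0.01), adjusted over the 24 lists of a comparison, beside camera with an estimated correlation and fry. Camera compares a list with the other genes, while fry tests whether its genes move on balance one way. The lists were p53 target genes, apoptosis machinery, double-strand break repair, DNA replication and S phase, G2 and M phase, histone genes, pluripotency, neural and ectoderm markers, mesoderm markers, endoderm markers, trophectoderm markers, fibroblast and stromal markers, interferon response, NF-kB and inflammatory genes, immediate early genes, unfolded protein and integrated stress response, heat shock, oxidative stress and metallothioneins, hypoxia and glycolysis, cholesterol synthesis, Nodal and TGF-beta signalling, WNT signalling, ribosomal proteins, and lysosome and autophagy. Some genes are in more than 1 list. The pluripotency list shares 5 members with the Nodal list, and the unfolded protein list shares 1 with the p53 list.

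Named genes followed a rule fixed before the data were examined. It took up to 12 genes each way per dose past adjusted p 0.05 with the 3 irradiated arrays on the same side of the 3 controls, which none met. From each list it took at most 2 members of smallest p where none passed, and CDKN1A, MDM2, POU5F1, NANOG and SOX2 were always given. A further gene of the rule is not reported here. As no dose had calls, the rule did not say at which dose to take members. They were then taken at each dose at which the list passed, and at every dose for the p53 and pluripotency lists. That reading, and the naming of p53 members that passed when adjusted over the list alone, were chosen after the data were seen. FAP, chosen by the rule at 0.4 Gy, was not well above background on the arrays of a group and is given no value.

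The arrays' scan days and slides, numbered in order, were used as fixed blocks where a batch held more than 1 group, and values within such batches were computed. Alternatives tried were other background corrections, normalizations, filters, probe rules, thresholds and fits, the series matrix, the Cy5 channel alone and leaving out each array. Those added after the data were seen were scan day and slide in the list tests, median Cy5 signal as a covariate, comparisons within a day, pooled or linear doses, scan day in the scores of all lists, and the lists of 2 against 0.4 Gy without 0.4 Gy replicate 3. A named gene's change of sign was counted as a reversal only where its value exceeded its standard error. The tests of genes and lists were tested on simulated data with known changes. A list of 49 genes drawn at random, the size of the p53 list, was raised by 0.5 on the log2 scale. It was recovered for each comparison, the largest camera p being 4.7e-23 at 4 Gy against control. The simulated noise was independent between genes and equally wide in all groups, so recovery in the real data may be lower.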

Results

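Gene expression was measured in H9 cells, a human embryonic stem cell (hESC) line grown without feeder cells, 24 h after exposure to gamma rays from a cesium source. The 4 groups were non-irradiated controls and cells given 0.4, 2 or 4 Gy, with 3 replicates each and 12 arrays in all. Each array carried the Cy5 signal of a sample and the Cy3 signal of a pooled reference RNA, and 25302 genes were tested. The median Cy5 signal ran from 108 to 687 intensity units between arrays, and from 62.3% to 85.7% of the spots were well above background in Cy5. The number of arrays limits the precision, with a median standard error of 0.22 on the log2 scale for each dose against control. Pairs of arrays correlated at r = 0.221 to 0.890 across probes, which are not independent replicates. The third replicate of the 0.4 Gy group stood apart, with a mean r of 0.360 against the other 11 arrays, where the other arrays had 0.624 to 0.722. The arrays were scanned on 3 days and lay on 5 slides. Day 1 held 2 controls and the 3 arrays at 0.4 Gy, day 2 held 1 control and 1 array at 4 Gy, and day 3 held the 3 arrays at 2 Gy and 2 arrays at 4 Gy. No 2 Gy array therefore shared a day with a control.

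The title of the series asks how ionizing radiation affects self-renewal and pluripotency in these cells. At the highest dose, 4 Gy against control, the target genes of the p53 transcription factor rose together, with 48 of 49 members positive and a median log2 fold change of 0.55. RPS27L, a ribosomal protein S27 paralogue, was at 1.65 ± 0.29 (SE, n = 3 arrays per group). SPATA18, which acts in mitochondrial quality control, was at 1.44 ± 0.34, and PHLDA3, an inhibitor of AKT signalling, was at 1.41 ± 0.44. The TRAIL receptor genes TNFRSF10C and TNFRSF10B were at 1.41 ± 0.41 and 0.79 ± 0.17. DDB2, which recognises ultraviolet damage in nucleotide excision repair, was at 1.17 ± 0.33, and FDXR, a mitochondrial ferredoxin reductase, was at 1.01 ± 0.23.

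The p53 list passed limma's camera test at 4 Gy with an adjusted p of 2.7e-34, and with an adjusted p of 9.9e-04 under an estimated correlation. Limma's fry test gave an adjusted p of 0.003. No member passed over all genes, and 10 members passed when adjusted over the list alone, namely the 7 above with PLK3 (0.95 ± 0.22), ASCC3 (0.78 ± 0.17) and PTP4A1 (0.84 ± 0.25). All 10 were higher on the 3 irradiated arrays than on any control array. They were chosen by their p on these same arrays, so this adds no support. CDKN1A, the cell cycle inhibitor p21, was at 0.81 ± 0.34 with an adjusted p of 0.082 over the list alone. MDM2, the ubiquitin ligase of p53, was at 0.30 ± 0.13 with an adjusted p of 0.089 over the list alone, and was well above background on 2 of the 3 control arrays. The probe for RPS27L lay on chromosome 15, at 61234919 to 61234978 of hg18, and that for SPATA18 on chromosome 4, at 52657932 to 52657991. The other probes for SPATA18 gave 0.07 and 0.47, so its probes disagreed. The second probes for TNFRSF10B, CDKN1A and MDM2 gave 0.45, 0.55 and 0.11. The other probes for ASCC3 gave 0.29 and 0.42 and those for PTP4A1 gave 0.45 and 0.44.

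The score of the p53 list on an array was the median of its members after each gene was centred on its mean over the 12 arrays. It was -0.287 ± 0.129 in controls, -0.219 ± 0.0305 at 0.4 Gy, 0.235 ± 0.0924 at 2 Gy and 0.330 ± 0.0999 at 4 Gy (SD, n = 3). All 3 arrays at 4 Gy lay above all 3 controls, with an exact permutation p of 0.1 (two-sided), the smallest that 3 arrays against 3 can give. With scan day as a block the list median at 4 Gy was 0.56, with a camera adjusted p of 6.7e-08. This value rested on day 2, where the 4 Gy array exceeded the control array in 43 of 49 members.

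**Figure D1:**
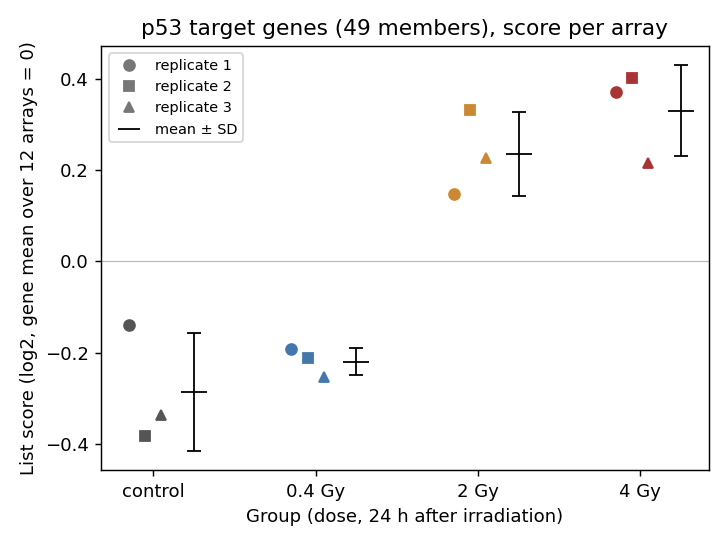
Score of the p53 target genes on each array (log2, each gene's mean over the 12 arrays set to 0) by dose group, with the 3 replicates as symbols and the group mean ± SD beside them. All arrays at 2 Gy (0.148 to 0.332) and 4 Gy (0.216 to 0.402) lay above all control arrays (-0.383 to -0.14) and all arrays at 0.4 Gy (-0.253 to -0.193).

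Without scan day as a block, other groups of genes moved less at 4 Gy than the p53 list. Double-strand break repair genes were lower in 27 of 34 members, with a median of -0.09 (camera adjusted p = 0.0044; adjusted p = 0.658 with an estimated correlation). Among them, XRCC5, the Ku80 subunit of end joining, was at -0.26 ± 0.13, and the nuclease gene EXO1 at -0.27 ± 0.17. DNA replication and S phase genes were lower in 32 of 41 members, with a median of -0.15 (camera adjusted p = 0.025; adjusted p = 0.658 with an estimated correlation), though the 2 members of smallest p were positive. These were TYMS, thymidylate synthase, at 0.62 ± 0.29 and TK1, thymidine kinase, at 0.30 ± 0.18. The unfolded protein and integrated stress response list was higher in 18 of 24 members, with a median of 0.22 (camera adjusted p = 0.0104; adjusted p = 0.658 with an estimated correlation). The chaperone genes CALR and HSP90B1 were at 0.64 ± 0.20 and 0.55 ± 0.24. The oxidative stress and metallothionein list was higher in 19 of 25 members, with a median of 0.20 (camera adjusted p = 0.042; adjusted p = 0.658 with an estimated correlation). GPX1, a glutathione peroxidase, was at 0.34 ± 0.13 and GCLM, which acts in glutathione synthesis, at 0.62 ± 0.37. XRCC5 was at -0.16 without 4 Gy replicate 1, EXO1 at -0.18 without 4 Gy replicate 2, and GCLM at 0.35 without control replicate 3 and 0.96 without control replicate 2. In each of these 4 lists, 0 members passed over all genes and 0 when adjusted over the list alone. With median centring in place of loess, the last 2 lists turned to medians of -0.12 and -0.08, while the repair and replication lists fell further, to -0.28 (32 of 34 lower) and -0.47 (39 of 41 lower). TK1 and GPX1 turned with it to -0.11 and -0.07, and another probe for HSP90B1, kept by a stricter filter, gave -0.07. With scan day as a block the repair and replication lists no longer passed (camera adjusted p = 0.0693 and 0.0961), though their medians stayed at -0.09 and -0.17, with 19 of 34 and 29 of 41 members lower. The block rests on the pair of arrays of day 2, 1 from each group. In it the unfolded protein list was at 0.83, with 22 of 24 members higher (camera adjusted p = 8.8e-04), above the 0.56 of the p53 list, and the oxidative stress list was at 0.49. Lists that did not pass without the block also moved far in this pair, such as fibroblast and stromal markers at -0.78 and endoderm markers at 0.54. Of the 5 lists that passed at 4 Gy, the p53 list included, 2 still passed without control replicate 3, 3 without 4 Gy replicate 1 and 3 without 4 Gy replicate 3. The replication median was -0.08 without 4 Gy replicate 1, that of the unfolded protein list 0.12 without 4 Gy replicate 3, and that of the oxidative stress list 0.10 without control replicate 3. The repair median was -0.15 without 4 Gy replicate 1. The oxidative stress list also lost its call without 2 Gy replicate 1 (adjusted p = 0.0557). With the processed signals, 2 of the 5 lists still passed, the p53 and repair lists. With the Cy5 yield as a covariate 3 still passed, these 2 and the unfolded protein list.

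Over all genes, limma called 0 genes at 4 Gy against control. At an unadjusted p under 0.05 there were 373 genes, where 1265 were expected by chance. Array quality weights called 3 genes and scan day as a block called 1. In simulated data with each gene's spread over these arrays, 43% of genes changed by a log2 fold of 1 and 83% of those changed by 2 were recovered for this comparison. The simulated noise was independent between genes and equally wide in all groups. The count of 373 against 1265 shows that the real arrays depart from such noise. The recovered shares may therefore be too high, here and at the other doses.

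At 2 Gy against control the same list of p53 target genes rose, with 47 of 49 members positive and a median log2 fold change of 0.54. RPS27L was at 1.55 ± 0.29, TNFRSF10C at 1.35 ± 0.41 and SPATA18 at 1.31 ± 0.34. FDXR and PLK3, a polo-like kinase, were both at 0.98, with standard errors of 0.23 and 0.22. MDM2 was at 0.53 ± 0.13, while its second probe gave 0.09. The other probes for SPATA18 gave 0.01 and 0.42. CDKN1A was at 0.60 ± 0.34, and at 0.24 without 2 Gy replicate 2 and 0.94 without 2 Gy replicate 1.

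The p53 list passed camera at 2 Gy with an adjusted p of 4.8e-16, and with an adjusted p of 0.014 under an estimated correlation. Fry gave an adjusted p of 0.012. No member passed over all genes, and 8 passed when adjusted over the list alone, namely RPS27L, TNFRSF10B (0.75 ± 0.17, second probe 0.35), TNFRSF10C, PLK3, FDXR, SPATA18, MDM2 and ASCC3 (0.67 ± 0.17), a helicase subunit. DDB2 was at 1.04 ± 0.33, with an adjusted p of 0.051 over the list alone. The 3 arrays scored above all 3 controls (exact permutation p = 0.1, two-sided, the smallest possible). With scan day as a block the list median was 0.38 (camera adjusted p = 4.2e-04). That value reached the controls only through the 4 Gy arrays, and no value within a day could be had, since 2 Gy and control shared none.

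**Figure D2:**
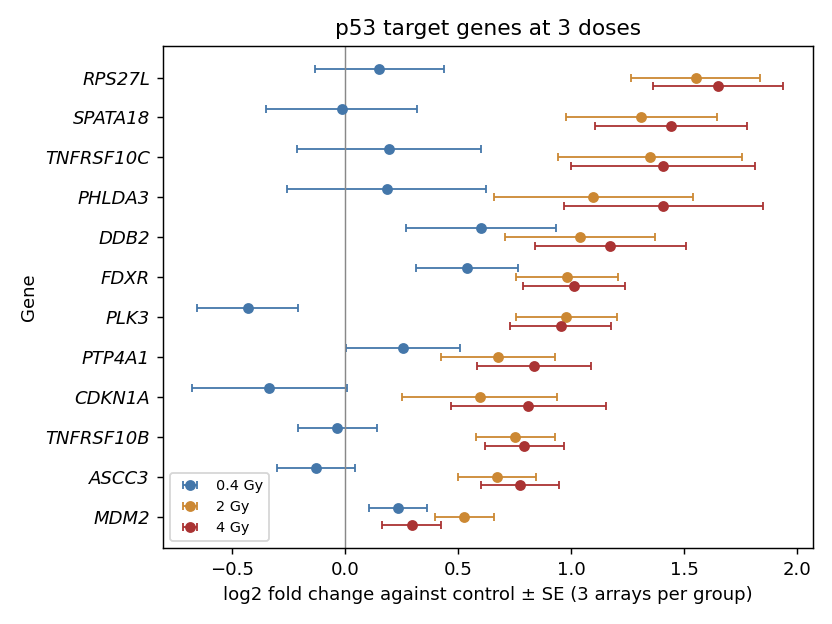
Log2 fold change against control (horizontal axis, ± SE, 3 arrays per group) of CDKN1A, MDM2 and the p53 target genes that passed when adjusted over the list alone at 2 or 4 Gy, with 1 colour per dose. RPS27L stood at 1.55 at 2 Gy and 1.65 at 4 Gy, against 0.15 at 0.4 Gy.

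The unfolded protein and integrated stress response list was the other list that passed camera at 2 Gy. It was higher in 20 of 24 members with a median of 0.34 (camera adjusted p = 0.018; adjusted p = 1.00 with an estimated correlation). CALR was at 0.78 ± 0.20 and SESN2, a stress-induced regulator of mTORC1 that is also in the p53 list, at 0.60 ± 0.24. No member passed over all genes or when adjusted over the list alone. The call was lost without control replicate 3 (median 0.08, adjusted p = 0.201), where SESN2 was at 0.37, and without 2 Gy replicate 2 (median 0.07, adjusted p = 0.765), while the median was 0.66 without 2 Gy replicate 1. It was also lost with median centring (median 0.08, adjusted p = 0.827), the processed signals (median 0.29, adjusted p = 0.0577) and the Cy5 yield as a covariate (median 0.19, adjusted p = 0.11), while scan day and slide as blocks gave medians of 0.96 and 0.84. Its size was thus not settled.

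Over all genes, limma called 0 genes at 2 Gy against control, with 1067 at an unadjusted p under 0.05 and 1265 expected by chance. Array quality weights called 38 genes, 33 up and 5 down, and the Cy5 channel alone called 1. In simulated data 47% of genes changed by a log2 fold of 1 and 78% of those changed by 2 were recovered for this comparison.

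At 0.4 Gy against control the p53 target genes were split evenly, with 24 of 49 positive and a median of -0.00, while the test leaned up (camera adjusted p = 0.25). RPS27L was at 0.15 ± 0.29 and CDKN1A at -0.33 ± 0.34, while FDXR and DDB2 were at 0.54 ± 0.23 and 0.60 ± 0.33. MDM2 was at 0.23 ± 0.13. PLK3 was at -0.43 ± 0.22. Without 0.4 Gy replicate 3, FDXR, DDB2, PLK3 and CDKN1A were at 0.27 ± 0.18, 0.24 ± 0.29, -0.16 ± 0.17 and -0.14 ± 0.37. No member passed over all genes or when adjusted over the list alone. The list did pass camera without control replicate 1 (adjusted p = 0.0265), without 0.4 Gy replicate 3 (adjusted p = 0.0307), with slide as a block (adjusted p = 0.0422) and after scaling between arrays (adjusted p = 0.00384, with 35 of 49 members positive and a median of 0.11). A small rise at this dose was thus not excluded. Within day 1 the median was -0.03 over 3 irradiated and 2 control arrays.

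Lists of cell state genes passed camera at 0.4 Gy, but not the tests set against the spread between arrays. Pluripotency genes were higher in 35 of 42 members, with a median of 0.38, and mesoderm markers were lower in 28 of 30, with a median of -0.84. Both had a camera adjusted p of 2.1e-06, and both had an adjusted p of 0.514 with an estimated correlation. Fibroblast and stromal markers (22 of 24 lower, median -0.81) and endoderm markers (22 of 23 lower, median -0.58) had camera adjusted p values of 4.3e-05 and 0.0012, with adjusted p = 0.514 and 0.563 under an estimated correlation. Fry gave adjusted p of 0.61 for the pluripotency, mesoderm and fibroblast lists and 0.73 for the endoderm list. Their array scores gave exact permutation p of 0.3, 0.4, 0.2 and 0.6 in that order (two-sided), where 0.1 is the smallest possible. In the pluripotency list, PRDM14 was at 0.82 ± 0.35 and USP44, a deubiquitinase, at 1.47 ± 0.67. PRDM14 was well above background on 2 of 3 arrays in each group. Desmin (DES) was at -0.87 ± 0.26, the blood regulator RUNX1 at -0.92 ± 0.36, the stromal marker S100A4 at -1.05 ± 0.52 and SOX17, an endoderm regulator, at -1.96 ± 1.29. CDX2 was at -0.62 ± 0.29 and well above background on 1 of the 3 irradiated arrays, and it was at -0.36 without control replicate 3.

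These shifts moved with the array that stood apart. 0.4 Gy replicate 3 had a pluripotency score of 0.837 and a mesoderm score of -1.61, where the other 11 arrays lay between -0.477 and 0.263 and between -0.222 and 0.573. Without it, the mesoderm, endoderm and fibroblast lists did not pass (camera adjusted p = 0.325, 0.407 and 0.0994). The endoderm median then turned to 0.12 with 18 of 23 members higher, while the fibroblast median was -0.47 with 21 of 24 lower, and the median of the pluripotency list was 0.153 with the call kept. Of the 28 genes named at this dose by the rule, 19 turned or moved by over 1.5 times without it. PRDM14 was then at 0.33, USP44 at 0.60 and RUNX1 at -0.43. SOX17 was at 0.07 without it, and DES was at 0.06 after scaling between arrays. Within slide 2, the medians were 0.12 for pluripotency and -0.17 for mesoderm over 3 irradiated arrays and 1 control, and with slide as a block neither list passed (camera adjusted p = 0.145 and 0.208). Within day 1 they were 0.30 and -0.68.

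Another 7 lists passed camera at 0.4 Gy, and none of them did so with an estimated correlation. The WNT signalling list was lower in 19 of 24 members (median -0.49, camera adjusted p = 0.0033; adjusted p = 0.514 with an estimated correlation), with WNT3A at -0.80 ± 0.25 and WNT5B at -0.54 ± 0.29. Immediate early genes were lower in 17 of 20 (median -0.40, camera adjusted p = 0.011; adjusted p = 0.514 with an estimated correlation), with FOSB at -0.42 ± 0.20 and JUNB at -0.96 ± 0.52. NF-kB and inflammatory genes were lower in 17 of 21 (median -0.25, camera adjusted p = 0.0048; adjusted p = 0.514 with an estimated correlation), with the cytokine gene IL6 at -0.82 ± 0.41, and at -0.25 ± 0.24 without 0.4 Gy replicate 3. BIRC3 was at -0.34 ± 0.19 and well above background on 1 irradiated array, and it turned to 0.17 in the Cy5 channel alone. Hypoxia and glycolysis genes were lower in 22 of 28 (median -0.21, camera adjusted p = 0.018; adjusted p = 0.563 with an estimated correlation), with ANKRD37 at -1.04 ± 0.31 and PGK1, phosphoglycerate kinase, at -0.41 ± 0.20. Histone genes were lower in 18 of 23 (median -0.17, camera adjusted p = 0.0033; adjusted p = 0.514 with an estimated correlation), with H2BC15 at -0.41 ± 0.13 and H1-2 at -0.71 ± 0.26. DNA replication and S phase genes were higher in 31 of 41 (median 0.14, camera adjusted p = 0.0014; adjusted p = 0.563 with an estimated correlation), with the replicative helicase genes GINS1 and GINS4 at 0.65 ± 0.21 and 0.48 ± 0.18. G2 and M phase genes were higher in 32 of 40 (median 0.12, camera adjusted p = 0.011; adjusted p = 0.748 with an estimated correlation), while the members of smallest p went both ways, CDK1 at -0.44 ± 0.27 and the spindle checkpoint kinase TTK at 0.35 ± 0.21, which turned to -0.05 with array quality weights. No member of any of the 11 lists that passed at this dose did so over all genes or when adjusted over the list alone. Of the 11 calls, 2 were kept without 0.4 Gy replicate 3, 7 without control replicate 2, 7 without control replicate 3, 9 without 0.4 Gy replicate 1 and 10 without control replicate 1. Without 0.4 Gy replicate 3 the replication median turned to -0.08 with 16 of 41 members higher, the G2 and M phase median was 0.00 with 20 of 40 higher, and those of WNT signalling, immediate early and NF-kB genes were -0.16, -0.14 and -0.11, while the hypoxia median was -0.23 with its call lost. The replication, G2 and M phase and histone medians were 0.08, 0.06 and -0.09 without control replicate 2. Without control replicate 1 the hypoxia median was -0.05 (adjusted p = 0.672) and PGK1 was at -0.18, and without control replicate 3 JUNB was at -0.52. With scan day as a block 7 were kept and with slide as a block 5. Within day 1 all 11 medians kept their signs, and within slide 2 those of 10 lists did. Both batches hold all 3 arrays at 0.4 Gy, and day 1 lacks only control replicate 3. Kept signs were thus likely beforehand, and they do not test the part of 0.4 Gy replicate 3.

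Over all genes, limma called 0 genes at 0.4 Gy against control, with 683 at an unadjusted p under 0.05 and 1265 expected by chance. Array quality weights called 3 genes. In simulated data 42% of genes changed by a log2 fold of 1 and 80% of those changed by 2 were recovered for this comparison.

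The core pluripotency factors varied widely between replicates in some groups, and none passed at any dose (limma adjusted p = 1.00). Their standard errors rest on a spread shared by all groups. As log2 ratios to the reference, POU5F1 ran from -1.20 to 3.15 at 0.4 Gy but from -1.06 to -0.77 at 2 Gy. POU5F1 (OCT4) was at 1.37, -0.67 and -1.15 at 0.4, 2 and 4 Gy, each with a standard error of 0.94. Its other probes gave 1.153 to 1.281 at 0.4 Gy, -1.218 to -1.338 at 2 Gy and -1.355 to -1.385 at 4 Gy. NANOG was at 0.82, -0.13 and -0.28, with a standard error of 0.94, and SOX2 was at 1.19, -0.89 and -0.67, with a standard error of 1.08. The 0.4 Gy value of SOX2 turned to -0.21 without 0.4 Gy replicate 3, NANOG turned with 1 array left out at each dose (to -0.04 at 0.4 Gy without control replicate 3), and the 4 Gy value of POU5F1 turned to 1.08 with scan day as a block. POU5F1 has near-identical pseudogene copies that its probes may not tell apart. The pluripotency list as a whole had medians of -0.05 at 2 Gy and 0.06 at 4 Gy and passed at neither dose (camera adjusted p = 0.875 and 0.872), with the test at 2 Gy leaning up. With scan day as a block, however, the list was higher at 2 and 4 Gy, with medians of 0.69 and 0.46 (camera adjusted p = 1.4e-04 and 8.5e-04), so that its direction at these doses was not settled. Within day 2 the median at 4 Gy was 0.46 over 1 array each. PODXL, the podocalyxin gene, was at 0.89 ± 0.23 at 2 Gy and 0.61 ± 0.23 at 4 Gy, LIN28B was at -0.70 ± 0.33 at 4 Gy, and UTF1 was at 0.73 ± 0.23 at 2 Gy. The value of UTF1 compares 1 array at 2 Gy with 2 controls, since its spots on the others were left out as outliers, and it turned to -0.73 in the series matrix.

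**Figure D3:**
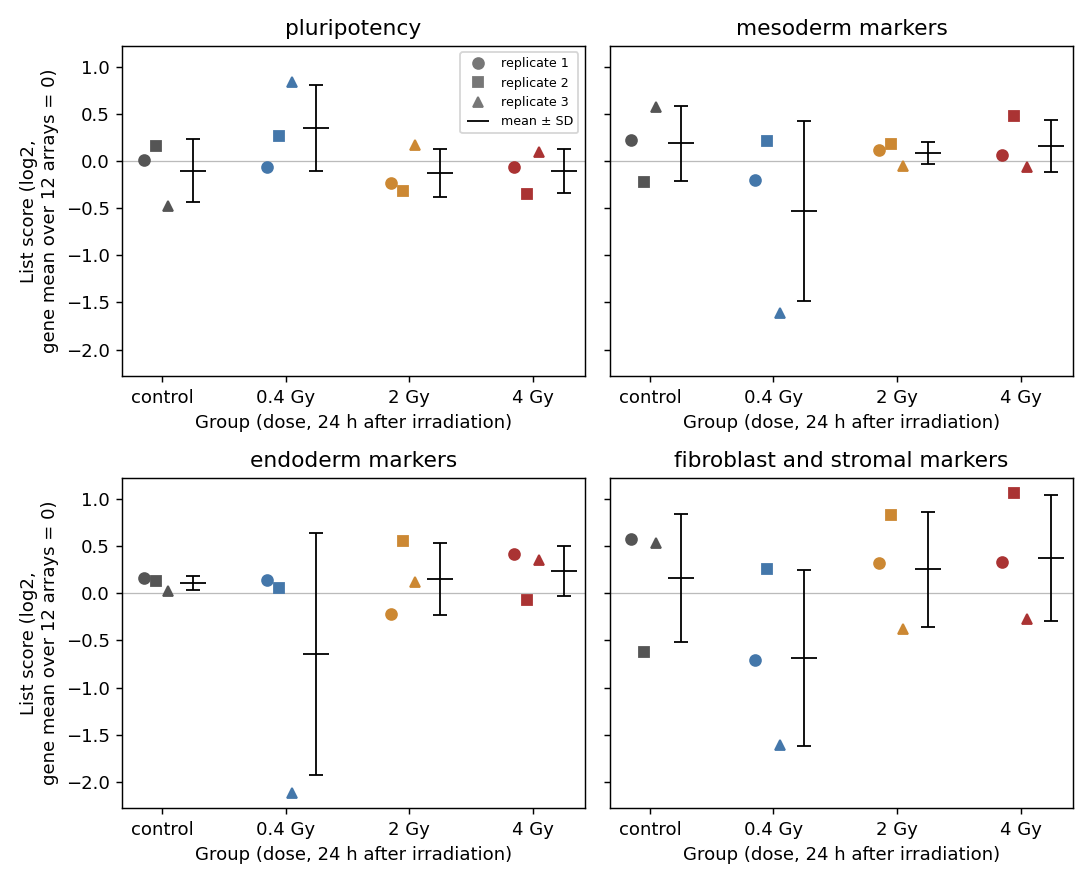
Scores of the pluripotency, mesoderm, endoderm, and fibroblast and stromal lists on each array (log2, each gene's mean over the 12 arrays set to 0) by dose group, with the 3 replicates as symbols and the group mean ± SD. The third array at 0.4 Gy lay farthest from the rest, at 0.837 for pluripotency, -1.61 for mesoderm, -2.12 for endoderm and -1.61 for fibroblast and stromal markers.

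The comparison of 2 Gy with 0.4 Gy tested the difference between successive doses. The p53 target genes were higher at 2 Gy in 43 of 49 members, with a median of 0.44 (camera adjusted p = 2.7e-07; adjusted p = 0.148 with an estimated correlation; fry adjusted p = 0.019). PLK3 differed by 1.41 ± 0.22 and RPS27L by 1.40 ± 0.29, and all 3 arrays at 2 Gy lay above all 3 at 0.4 Gy in the list score (exact permutation p = 0.1, two-sided, the smallest possible). No member passed over all genes, and 7 passed when adjusted over the list alone. Limma called 1 gene, which was higher at 2 Gy, with 2392 genes at an unadjusted p under 0.05. It was the transcript AK095453 at chromosome 11, 33684480 to 33684539 of hg18, at 1.17 ± 0.12 (adjusted p = 0.036), which has no current symbol and was named here after its values were seen. The count stayed at 1 in 10 of 35 other settings and was 0 with scan day as a block, and the direction of AK095453 turned to -0.11 in the Cy5 channel alone. The 2 groups shared no scan day, and with it as a block the p53 score differed by 0.359 ± 0.173 (SE), against 0.455 without.

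From 2 to 4 Gy no list passed and limma called 0 genes, with 130 genes at an unadjusted p under 0.05 and 0 called in every other setting run. The p53 target genes were higher at 4 Gy in 39 of 49 members, with a median of 0.10 (camera adjusted p = 0.24) and 0.13 within day 3, where 37 of 49 were higher over 2 and 3 arrays. ZMAT3, an RNA-binding zinc finger gene, differed by 0.38 ± 0.17 and TRIAP1, an inhibitor of apoptosis, by 0.38 ± 0.20. The list scores overlapped (exact permutation p = 0.3, two-sided).

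The changes at 2 and 4 Gy were compared across all 25302 genes, which are not independent replicates. Their log2 fold changes correlated at r = 0.816, where unchanged groups simulated against the same 3 controls gave 0.50. The covariance was 0.0555 against 0.0558 in the simulation, a difference of -2.7e-04. No calls were shared, and 268 genes had an unadjusted p under 0.05 in the same direction at both doses, against 314 in the simulation and 8.52 for independent lists. The covariance and the shared genes were no higher than in the simulation, while r and the share of genes of the same sign (78% against 66.65%) were higher. The simulation drew independent noise, equally wide in all groups, and the controls are too few to split. Whether shared controls account for the likeness of 2 and 4 Gy could therefore not be told. Day 3 also held the 3 arrays at 2 Gy and 2 arrays at 4 Gy, but no control or 0.4 Gy array. The part of a shared scan day in this likeness was not tested. The changes at 0.4 Gy correlated with those at 2 Gy at r = -0.01 and at 4 Gy at r = -0.11, where the simulation gave 0.50 for each. Their covariances were -0.0012 and -0.0078, against 0.0559 and 0.0557. The simulation thus did not describe the arrays at 0.4 Gy, which limits its use for the other doses.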

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

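Tests chosen only after the result was seen were both tests of the 0.4 Gy cell state pattern and the test of Cy5 yield for 0.4 Gy replicate 3. The scan day and Cy5 yield tests of the p53 rise were also chosen after the data were seen, with predictions written before their own results.

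The 0.4 and 2 Gy groups differed in 9 gene lists by camera, and in none of them with an estimated correlation. The p53 target genes were higher at 2 than at 0.4 Gy (median 0.44, 43 of 49 members, adjusted p = 2.7e-07; adjusted p = 0.148 with an estimated correlation). Double-strand break repair genes were lower at 2 Gy (median -0.15, 26 of 34, adjusted p = 0.00269; adjusted p = 0.41 with an estimated correlation). DNA replication and S phase genes were lower (median -0.29, 34 of 41, adjusted p = 1.3e-04; adjusted p = 0.598 with an estimated correlation). Pluripotency genes were lower (median -0.36, 28 of 42, adjusted p = 0.00269; adjusted p = 0.598 with an estimated correlation). Mesoderm markers were higher (median 0.69, 26 of 30, adjusted p = 0.00271; adjusted p = 0.598 with an estimated correlation), as were endoderm markers (median 0.56, 21 of 23, adjusted p = 0.019; adjusted p = 0.615 with an estimated correlation). Fibroblast and stromal markers were higher (median 0.93, 22 of 24, adjusted p = 0.0016; adjusted p = 0.598 with an estimated correlation). NF-kB and inflammatory genes were higher (median 0.30, 16 of 21, adjusted p = 0.0335; adjusted p = 0.598 with an estimated correlation), and so were immediate early genes (median 0.64, 18 of 20, adjusted p = 0.00104; adjusted p = 0.41 with an estimated correlation). The 2 groups shared no scan day or slide. Without 0.4 Gy replicate 3, a check chosen after the data were seen, 2 of the 9 lists still passed, the p53 list (median 0.393, adjusted p = 1.5e-08) and the immediate early genes (median 0.353, adjusted p = 0.046). The mesoderm and endoderm medians were then 0.0557 and -0.0875, so these differences rested on that array. The replication, NF-kB and repair medians shrank to -0.0626, 0.112 and -0.0838. The pluripotency median was -0.277 (27 of 42 lower, adjusted p = 0.112) and the fibroblast median 0.461 (22 of 24 higher, adjusted p = 0.112).

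The rise of the p53 target genes at 2 and 4 Gy was weighed against 3 technical explanations. Whether scan day accounts for the rise at 4 Gy could not be told. With it as a block the median was 0.559 (camera adjusted p = 6.7e-08) and the list score differed by 0.552 ± 0.128 (SE), which met the value set beforehand against scan day. That bound was too weak, because the value rests on 1 array of each group from the same day, and other lists moved about as far within that pair, such as the unfolded protein list at 0.829, fibroblast markers at -0.781, interferon response genes at 0.527 and cholesterol synthesis genes at -0.525. Over its own standard error, the p53 score difference with the block was the largest of the 24 lists (ratio 4.32). The interferon response genes were next (3.70), though their score differed by 0.0693 without the block. For the unfolded protein, cholesterol synthesis and fibroblast lists the ratios were 1.21, -1.43 and -0.742. 2 Gy had no day with a control. Cy5 yield did not account for the rise at 4 Gy, as the median with the yield as a covariate was 0.607, and no array carried it, as the lowest median with 1 of the 6 arrays left out was 0.533. Of the 10 splits of the 6 arrays, the real medians of 0.544 at 2 Gy and 0.55 at 4 Gy were matched by 1 split each, the real one, against highest others of 0.316 and 0.351, and these splits are too few for a share under 0.05. The pair of arrays of day 2 shared scan day and slide, so scan day cannot have made their difference. With 1 array of each group, that difference could not be told from the spread between single arrays. At 2 Gy an effect of dose could not be told from scan day. At 4 Gy the rise outside that pair could not be told from it either.

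The lower markers of differentiated cells and higher pluripotency genes at 0.4 Gy may come from 1 array. Without 0.4 Gy replicate 3, the mesoderm list had a camera adjusted p of 0.325 and the pluripotency median was 0.153. For a differing share of differentiated cells among the control cultures, the mesoderm score spanned 0.796 within the 3 controls, while the group means differed by 0.724. That met the value set for this cause, but the comparison cannot decide it. The share itself was not measured, and the lowest and highest controls were scanned on different days. The difference of the means also moved with 0.4 Gy replicate 3. A dose effect on cell state was not tested apart from these and stays open.

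The low correlation of 0.4 Gy replicate 3 with the other arrays was weighed against poor hybridization and low yield. Its reference channel correlated with those of the others at a mean r of 0.989, rank 7 of 12, which met neither value set beforehand. The arrays ran from 0.9865 to 0.9908, and control replicate 1, the lowest, did not stand apart in its ratios (mean r 0.717). The reference channel thus showed no sign of a fault of the whole array. Its median Cy5 signal was 247, above the median of the 12 arrays at 169, which argues against low yield. As log2 ratios to the reference, SOX2 was at 1.97 and SOX17 at -4.275 on this array. On the other arrays, controls included, they ran from -3.52 to -1.25 and from 1.28 to 2.29. A culture that held fewer differentiated cells may account for the low marker scores of 0.4 Gy replicate 3, but only these expression values bear on it. The cell state of the other cultures was not tested either.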

How the results depend on the processing

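Scan day and slide in the list tests and list scores, the Cy5 yield covariate, pooled or linear doses, and the lists of 2 against 0.4 Gy without 0.4 Gy replicate 3 were tests chosen only after the data were seen. For the rest the cause was not tested. The p53 list kept its direction and call in all 20 alternatives at 2 Gy (medians 0.364 to 0.642, adjusted p up to 0.014) and at 4 Gy (0.404 to 0.675, adjusted p up to 0.00295), and over 9 scalings. In several of the 20 the median could not move. These were the estimated correlation, fry, the replicate block and leaving out an array of a group not compared. Among the scalings, Aquantile left the ratios as in the main fit. At 0.4 Gy it passed with slide as a block (adjusted p = 0.0422), and with 1 array left out its adjusted p ran from 0.0265 to 0.787. Pluripotency at 0.4 Gy had adjusted p = 0.514 with an estimated correlation, 0.615 by fry and 0.145 with slide as a block. With scan day and slide as blocks it passed upward at 2 Gy (1.4e-04 and 5.7e-04) and 4 Gy (8.5e-04 and 6.1e-04). These values rest on 1 pair of arrays, with control replicate 3 as its control. The unfolded protein list at 2 Gy ran from a median of 0.0743 without 2 Gy replicate 2 to 0.958 with scan day as a block.

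Array quality weights called 3, 38 and 3 genes at 0.4, 2 and 4 Gy against control and 32 for 2 against 0.4 Gy. RPS27L was among those called at 2 and 4 Gy against control. The Cy5 channel alone called 1 at 2 Gy and scan day as a block 1 at 4 Gy. All 35 alternatives gave 0 to 38 calls at 2 Gy, 36 gave 0 to 3 at 0.4 Gy and 35 gave 0 to 3 at 4 Gy, while 4 against 2 Gy had 0 in all 36. The 1 call for 2 against 0.4 Gy went to 0 without background correction, with plain subtraction, offset 16, processed signals, median centring, scaling, the series matrix, the filter on all 12 arrays, only the 2 groups, a trend with robust eBayes, scan day, slide, and adjusted p below 0.01. The replicate block also brought it to 0. With 1 array left out it ran from 0 to 1, with 10 of the 12 arrays ending it. The filter and the 2-group fit use fewer genes and arrays.

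Replicate numbers gave no sign of pairing the samples. Deviations of arrays with the same number correlated at a mean of 0.0119 over 18 pairs, 8 of them above 0.1. Pairs of different numbers had a mean of -0.00413 over 36 pairs, 13 of them above 0.1. Of the 12 arrays, 5 correlated best with an array of their own number. With so few arrays per group, a weak pairing was not excluded. With the replicate block, 0 genes were called in every comparison, and the 11, 2 and 5 list calls at 0.4, 2 and 4 Gy were all kept.

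The pooled contrast of 2 and 4 Gy against control and 0.4 Gy called 17 genes, 3 with scan day as a block, and 0 with median centring, processed signals, dose as a straight line or its log as a straight line. With 1 array left out it ran from 1 to 65.

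By the direction of the camera test, reversed lists at 0.4 Gy were fibroblast markers (adjusted p = 0.677, though the median stayed below 0 at -0.0105) and hypoxia genes (0.258) with slide as a block, and replication genes (2.4e-06 to 0.965) and endoderm markers (5.1e-06 to 0.407) with 1 array left out, turning without 0.4 Gy replicate 3. At 4 Gy the unfolded protein (0.297) and oxidative stress (0.40) lists reversed with median centring. Reversed genes at 0.4 Gy were TTK at -0.0457 and SOX2 at -0.013 with array weights, DES at 0.0611 with scaling and BIRC3 at 0.17 in the Cy5 channel alone. With 1 array left out, SOX17 ran from -3.00 to 0.0659 and SOX2 from -0.21 to 2.25, each turning without 0.4 Gy replicate 3. UTF1 at 2 Gy was at -0.73 in the series matrix. At 4 Gy TK1 was at -0.11 and GPX1 at -0.0693 with median centring, HSP90B1 at -0.0655 with the filter on all 12 arrays, where another probe stood for it, and POU5F1 at 1.08 with scan day and with slide as a block. AK095453 for 2 against 0.4 Gy was at -0.11 in the Cy5 channel alone.

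Low signal limits the dimmer genes, since as few as 62.3% of spots were well above background in Cy5.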

Other observations

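The pooled and linear dose contrasts were chosen only after the results of the single doses were seen.

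Of the 24 gene lists, 9 passed at no dose against control. The lowest camera adjusted p for neural and ectoderm markers was 0.0546, at 4 Gy, with medians from -0.07 to 0.09 over the 3 doses. Apoptosis machinery had a lowest adjusted p of 0.0771, at 2 Gy, with medians from -0.07 to 0.15. Lysosome and autophagy genes had a lowest adjusted p of 0.091 and Nodal and TGF-beta signalling genes of 0.186, both at 4 Gy, with medians from -0.05 to 0.11 and from -0.17 to 0.23. For heat shock genes (lowest adjusted p = 0.24), trophectoderm markers (0.255), cholesterol synthesis genes (0.255), interferon response genes (0.488) and ribosomal proteins (0.604) all medians lay between -0.13 and 0.12. The interferon response genes had medians from -0.05 to 0.06.

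Because the p53 scores fell into a lower level in controls and at 0.4 Gy and a higher one at 2 and 4 Gy, 3 codings of dose were tried over the 12 arrays. Dose as a straight line called 0 genes by limma (1210 at an unadjusted p under 0.05) and the log2 of dose plus 1 called 0 (1437). The pooled contrast of 2 and 4 Gy against control and 0.4 Gy called 17 genes, all higher at the upper doses (2845 at an unadjusted p under 0.05). Of these, 6 have a current symbol and 5 are in the p53 list, namely RPS27L (1.52 ± 0.19), SPATA18 (1.38 ± 0.22), PLK3 (1.18 ± 0.17), TNFRSF10B (0.79 ± 0.11) and ASCC3 (0.79 ± 0.12). The other, ZIC1, was not well above background on any array at 2 or 4 Gy and is given no fold. This contrast was the coding with calls among those tried and grouped the doses after their scores were seen, so its calls are a hypothesis. With scan day as a block it called 3 genes, of which 1, a transcript without a current symbol, was among the 17. None of the 5 p53 list members passed with it (PLK3 fell to 0.69 ± 0.42 and TNFRSF10B to 0.48 ± 0.24, while RPS27L was at 1.69 ± 0.46, SPATA18 at 1.62 ± 0.54 and ASCC3 at 0.80 ± 0.29, with wider standard errors), and day 3 held 5 of the 6 arrays at the upper doses and none of the others. Of 100 drawn splits of the 12 arrays, 2 called at least 17 genes, the real one included, and the highest other called 224, which points to a structure of the samples. That split had each dose group on both sides, put 3 of the 4 arrays of slide 2 and 3 of the 4 of slide 4 on one side, and put the arrays of slides 1, 3 and 5 on the other. The cause of this was not tested.

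For the counts of genes, 10 splits of 6 arrays are too few for a share under 0.05. In the 4 comparisons with 0 calls, 0.4, 2 and 4 Gy against control and 4 against 2 Gy, all 10 splits gave 0, and for 2 against 0.4 Gy 1 split gave the real count of 1, the highest other being 0. For list medians taken as distances from 0, the p53 list at 0.4 Gy had 0.00269 against a highest other of 0.161, with 10 splits as large. The pluripotency list had 0.382 against 0.513 at 0.4 Gy (3 splits as large, the real one included), 0.0517 against 0.486 at 2 Gy (10 splits) and 0.0614 against 0.402 at 4 Gy (9 splits).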
